A study of Mus musculus with 24 samples.

How the data were processed

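RNA was measured by sequencing of polyadenylated transcripts in the CA1 subfield dissected from the hippocampus of C57BL/6J mice aged 3 to 5 months, per the labels. Per the labels' protocols, total RNA was extracted with TRI reagent and treated with DNase, and libraries were made with a TruSeq RNA kit. The protocols name cluster generation kits for both paired-end and single-end sequencing and do not say which library had which, so a difference between libraries in this respect was not tested. The TruSeq kit does not mark the strand, so reads of a gene and of an antisense transcript over it cannot be told apart. The 24 libraries fall into 4 groups by genotype and exposure, taken from the sample labels.

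The authors deposited 1 table of raw read counts per library, whole numbers per Ensembl gene with no normalization. Per the submitters' processing notes, STAR 2.3.0, HTSeq, DESeq2 and the genome build GRCm38.p2 were used, named without their roles. The annotation release, the strand setting of the counting and the version of DESeq2 are not given in the sources used here. Each count table lists 38355 genes and ends with 5 summary entries, for reads without a gene, ambiguous reads, reads of low quality, unaligned reads and reads without a unique position. These entries were left out of library sizes and tests. Of all reads in a table, those without a gene made up 7.58 to 10.36% per library, ambiguous reads 1.06 to 1.18%, and reads without a unique position 14.82 to 17.97%. Reads that match more than 1 place are thus not counted, and genes with near-identical copies, such as those of ribosomal proteins with many processed pseudogenes, may be undercounted.

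The authors also deposited 4 tables of pairwise comparisons made with DESeq2, per the series' design text. Per the file headers, they hold a mean normalised count per gene (a signal, the base mean), a log2 fold change with its standard error, and a p-value with an adjusted p-value. The lowest base mean in them is 10, and the deposited log2 fold change was nearer to 0 than the log2 ratio of the group means in 64 to 76.1% of genes per table. Below a base mean of 50 its median was 0.78 to 0.82 of that ratio. These tables were used for gene names, coordinates and a comparison of calls. Symbols came from the deposited tables for 16355 genes and from a reference name table for a further 20435, and 1565 genes stayed unnamed. A read was found for 27576 genes in at least 1 library. No per-sample column of the series tables was left out of use.

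Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust glmQLFit, glmQLFTest), with TMM normalization, filterByExpr at a minimum count of 10 and Benjamini-Hochberg adjustment. Genes with an adjusted p below 0.05 are said to have passed. Each of the 4 pairwise comparisons used only its own groups. A fit over all 24 libraries gave the genotype by novelty interaction, the genotype effect averaged over exposures and the novelty effect averaged over genotypes. Levels are CPM values, read counts scaled to a common library size after TMM, as mean ± SD over the libraries of a group, and the error of a log2 fold change is its standard error (SE).

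Altogether 21 gene lists and 16 marker lists of cell types and neighbouring tissues were fixed before the data were examined, as were the designs, the rule for named genes and most alternatives. The list of mitochondrially encoded genes matched none of the deposited identifiers and was not analysed here, which left 36 lists. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation and fry rotation tests were run beside it. Camera compares a list with all other tested genes, and fry asks whether a list's own genes move on balance to one side. Camera with the preset correlation was the main list test, and adjusted p-values with an estimated correlation are given beside it. In other splits of the same libraries into groups of the same sizes, it passed a median of 6 or 7 lists, depending on the comparison. A list that passed at the preset correlation alone is therefore weak evidence of a difference. As a further test, chosen after seeing the data, the mean log2 CPM of each list was compared between groups with an exact two-sided permutation test over all splits of the libraries. Genes belong to more than 1 list in places, among them Cdkn1a, Per1, Cnp and Etv1.

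Named genes follow a rule fixed in advance. Kat2a is always given. Then come, among genes that passed with a mean raw count of at least 50, a symbol that is not a predicted model or pseudogene and the same sign in every fit that leaves out 1 library, the 8 with the largest increase and the 8 with the largest decrease. From each list that passed camera or had at least 1 member that passed, up to 4 members with the smallest p were added. For the interaction, where no gene passed, the 3 with the smallest p are named. Some genes that the rule takes are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

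The alternatives were the size factors of DESeq2 or upper-quartile factors in edgeR, no filter on low counts, a mean of at least 10 reads, DESeq2 1.42.0, limma-voom, glmQLFit without robust estimation, a replicate block, 1 surrogate variable (sva 3.50.0), a single fit of all groups, an adjusted p below 0.1, and leaving out each library in turn. Chosen after seeing the data were the removal of each library's trend with GC content, the dentate marker level as a covariate, a term for libraries numbered 4 and above, and fits without control naive libraries 2 and 4. On simulated counts with 200 changed genes, edgeR recovered between 17.9% (interaction) and 68.7% (genotype average) of genes changed 1.25-fold, and between 74.2% (interaction) and 97% (novelty average) of those changed 2-fold. Unchanged genes made up 3.05% (genotype average) to 8.67% (novelty in cKO mice) of the simulated calls. Simulated counts were drawn independently for each gene and library, without shared trends such as that with GC content, so these shares may not hold for the real counts. The simulations ran on 16154 to 16650 genes, depending on the comparison. Among 61 pairs of libraries of the same group, none had identical counts and the lowest chi-square per degree of freedom was 3.73, so no library was taken for a repeat deposit of another. This does not show that libraries came from separate mice.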

Results

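Gene expression was measured in the CA1 subfield of the hippocampus, the field of pyramidal neurons from which most hippocampal output leaves, in mice with and without Kat2a in forebrain excitatory neurons. Kat2a encodes a lysine acetyltransferase of the SAGA and ATAC coactivator complexes. Control mice carried floxed Kat2a, and conditional knockout (cKO) mice carried in addition the Cre recombinase under the CamKII-alpha promoter, which is active in excitatory forebrain neurons. Mice of both genotypes were taken naive or after 15 min of novelty exposure. The 4 groups hold 6 control naive, 5 control novelty, 6 cKO naive and 7 cKO novelty libraries. The design asks which genes depend on Kat2a, which genes respond to novelty, and whether the response depends on Kat2a, in a study of hippocampal memory.

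Assigned reads per library ranged from 10.7 to 35.8 M (mega) reads with a median of 19 M. They were 10.7 to 23.4 M in control naive, 13.9 to 35.8 M in control novelty, 19.6 to 24.5 M in cKO naive and 13 to 21.2 M in cKO novelty libraries. The shallowest, control naive library 2, also stood apart on the second principal component, at 36.3 against at most 19.5 in any other library. The first 4 components held 14.8, 10.3, 8.2 and 7.4% of the variance. The share of reads without a unique position was 15.8 to 17.97% in control naive, 15.02 to 16.17% in cKO naive, 15.54 to 17.18% in control novelty and 14.82 to 15.74% in cKO novelty libraries. TMM normalization factors were 0.972 to 0.997 in control and 0.997 to 1.027 in cKO libraries. The slope of levels with GC content of the gene, set against the mean of all libraries, followed the library numbers of the titles. It was negative in 11 of 12 libraries numbered 1 to 3 and positive in 10 of 12 numbered 4 and above (two-sided permutation within groups over all cuts between numbers, chosen after seeing the data, p = 1e-05). Genotype effects averaged over exposures within these parts, which share no library, correlated across 13242 genes at r = 0.539 (Spearman rho = 0.543) and novelty effects at r = 0.461 (Spearman rho = 0.328). In the pairwise comparisons r was 0.213 for novelty in controls and 0.407 for novelty in cKO mice. It was 0.317 for genotype in naive mice and 0.383 for genotype after novelty. All 24 libraries had 0 to 9 reads of Xist, expressed from the inactive X chromosome, and 1073 to 2926 reads of the Y-linked Ddx3y. The labels do not say that libraries came from separate mice, so p-values measure only the spread between these libraries.

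Kat2a transcripts were lower in every cKO library than in every control library. Kat2a (ENSMUSG00000020918, GRCm38 chromosome 11, 100704746 to 100712465) measured 63.6 ± 3.98 CPM (SD, n = 6) in control naive, 60.2 ± 3.57 (n = 5) in control novelty, 36.2 ± 2.42 (n = 6) in cKO naive and 35.1 ± 2.26 (n = 7) in cKO novelty libraries. Single libraries lay between 56 and 70.3 CPM in controls and between 31.2 and 39.3 CPM in cKO mice. The cKO level was 56.9% of the control level in naive mice and 58.4% after novelty, with exact two-sided permutation p of 0.00216 over 924 splits and 0.00126 over 792 splits. The log2 fold change was -0.81 (SE 0.05, edgeR adjusted p = 2.75e-06) in naive mice and -0.77 (SE 0.05, edgeR adjusted p = 6.36e-07) after novelty. Novelty did not change Kat2a detectably, with a level of 94.7% of naive in controls (exact permutation p = 0.175) and 97.1% in cKO mice (exact permutation p = 0.446). The difference in mean log2 CPM was -0.82 in naive and -0.79 in novelty-exposed mice among libraries numbered 1 to 3, and -0.81 and -0.76 among those numbered 4 and above. Counts cover the whole gene, and whether reads fall in the deleted part is not known.

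**Figure D1:**
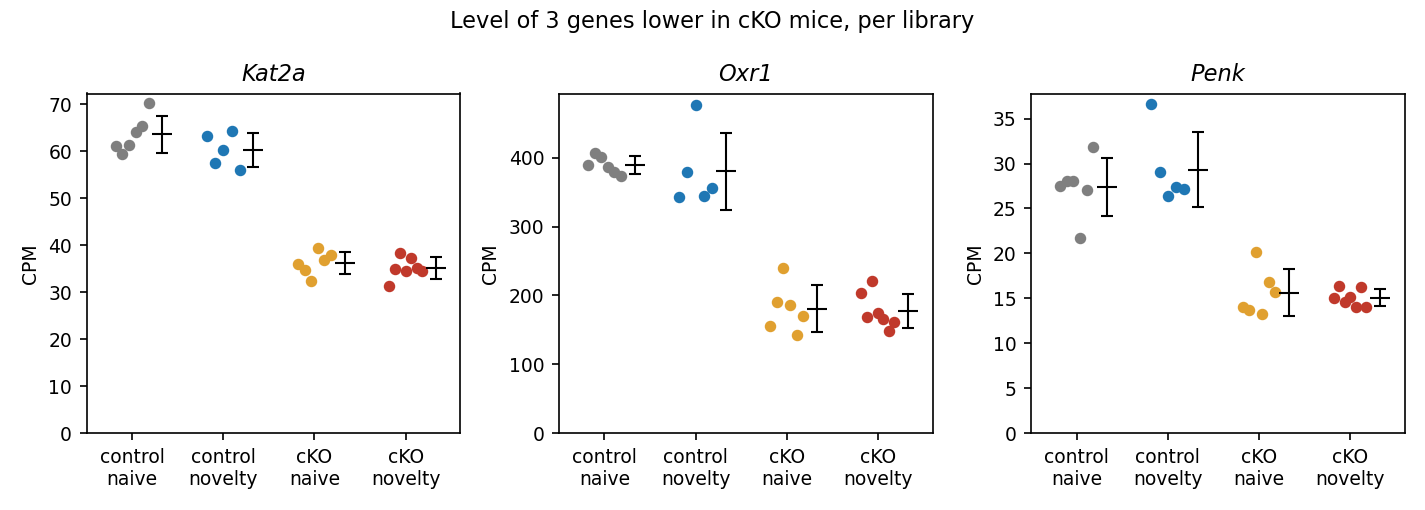
Level in CPM (vertical axes) of Kat2a, Oxr1 and Penk in each library of the 4 groups, with points for libraries and lines for the mean ± SD. Kat2a lies between 31.2 and 39.3 CPM in cKO libraries and between 56 and 70.3 CPM in control libraries.

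The first comparison asked which genes respond to novelty in control mice. Among named genes, transcripts of activity-induced transcription factors rose most, in 5 novelty against 6 naive libraries. Egr2 rose 18.4-fold (log2 4.20, SE 0.36), from 0.672 ± 0.338 to 12.6 ± 5.03 CPM, and Fos rose 9.59-fold (log2 3.26, SE 0.27), from 3.17 ± 1.36 to 31.3 ± 8.81 CPM. Egr2 (ENSMUSG00000037868) lies on GRCm38 chromosome 10 at 67535475 to 67542188, and Fos on chromosome 12 at 85473890 to 85477273. Egr1 rose from 83.2 ± 8.99 to 282 ± 41.6 CPM (log2 1.75, SE 0.10), and Homer1, a postsynaptic scaffold gene, rose from 131 ± 12.9 to 272 ± 22.5 CPM (log2 1.05, SE 0.07). Of 16100 genes tested, 196 passed in edgeR, 164 higher and 32 lower, and 62 of them changed more than 1.5-fold.

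Of 40 immediate early genes, 23 rose over all genes tested, and adjusted over the list alone 31 rose and 1 fell, namely the neuronal transcription factor gene Npas4, named after its values were seen. Fosb rose by 2.48 on the log2 scale (SE 0.16), Egr4 by 1.87 (SE 0.20), the nuclear receptor gene Nr4a1 by 1.15 (SE 0.15), Arc, which regulates synaptic AMPA receptors, by 1.10 (SE 0.14) and the kinase gene Sik1 by 1.05 (SE 0.10). The list median was 0.65 (camera adjusted p = 5.42e-48, adjusted p = 0.00368 with an estimated correlation). Of 15 glucocorticoid-responsive genes 5 rose, and 11 rose adjusted over the list alone. Its median was 0.43 (camera adjusted p = 1.91e-17, adjusted p = 0.012 with an estimated correlation). Among them were the kinase gene Sgk1 (1.01, SE 0.14), the period gene Per1 (0.97, SE 0.10; 56.0 ± 5.06 to 111 ± 18.7 CPM), the cell cycle inhibitor gene Cdkn1a (0.96, SE 0.18), Tsc22d3 (0.86, SE 0.08) and the EGF receptor inhibitor gene Errfi1 (0.77, SE 0.10). Of 18 circadian clock genes 3 rose, Per1, Per2 (0.56, SE 0.07) and Bhlhe40 (0.46, SE 0.06), and 5 rose adjusted over the list alone. Its median was 0.12 (camera adjusted p = 1.03e-06, adjusted p = 0.0199 with an estimated correlation).

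Of 24 heat shock and unfolded protein response genes, 3 chaperone or endoplasmic reticulum stress genes rose in control mice after novelty, Dnajb1 (0.53, SE 0.07), Hspa5 (0.30, SE 0.06) and Herpud1 (0.25, SE 0.06). Adjusted over the list alone 8 rose, with a median of 0.16 (camera adjusted p = 1.15e-06, adjusted p = 0.0829 with an estimated correlation). Of 18 p53 and DNA damage response genes 3 rose, Fas (1.02, SE 0.18), Cdkn1a and Sesn1, and 5 rose adjusted over the list alone. Its median was 0.08 (camera adjusted p = 0.000417, adjusted p = 0.0199 with an estimated correlation). Of 22 cholesterol synthesis genes 2 rose, among them Cyp51 (0.33, SE 0.06), and 4 rose adjusted over the list alone. Its median was 0.08 (camera adjusted p = 0.000417, adjusted p = 0.602 with an estimated correlation). Single members of lists that did not pass also changed. The glucose transporter gene Slc2a1 (0.53, SE 0.09), the NF-kappa-B inhibitor gene Nfkbia (0.56, SE 0.10), the melanocortin receptor gene Mc4r (0.79, SE 0.17) and Gpr161 (0.38, SE 0.09) rose, as did Plekhf1 (1.12, SE 0.19), which is in no list. Decreases were smaller, in Cd180 (-0.87, SE 0.17), the Notch target gene Heyl (-0.73, SE 0.15), Klhdc9 (-0.65, SE 0.15), the Notch ligand gene Jag1 (-0.46, SE 0.08) and Sox9 (-0.36, SE 0.06), a gene of astrocytes.

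Of the 32 named genes that passed in control mice after novelty, 24 passed in every edgeR fit that left out 1 library. Hspa5 and Gpr161 passed in 4 of 11 such fits, Herpud1 and Sesn1 in 3, Mc4r and Klhdc9 in 2, Heyl in 8 and Cd180 in 10. The count of 196 genes fell to 113 without control novelty library 2, 116 without control novelty library 5 and 128 without control naive library 6, and DESeq2 called 373.

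**Figure D2:**
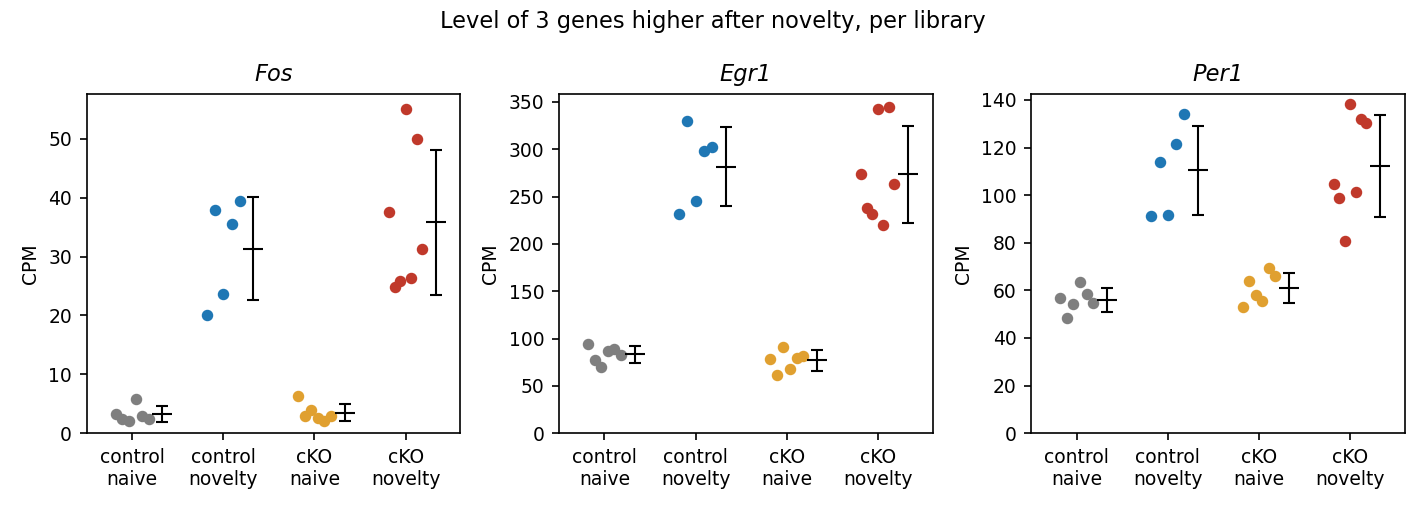
Level in CPM (vertical axes) of Fos, Egr1 and Per1 in each library of the 4 groups, with points for libraries and lines for the mean ± SD. Mean Fos was 3.17 CPM in control naive, 31.3 in control novelty, 3.49 in cKO naive and 35.8 in cKO novelty libraries.

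The same response was then measured in cKO mice, in 7 novelty against 6 naive libraries. Egr2 rose 23.8-fold (log2 4.57, SE 0.26) and Fos 10.3-fold (log2 3.36, SE 0.29), from 3.49 ± 1.51 to 35.8 ± 12.3 CPM. Homer1 rose from 114 ± 6.92 to 272 ± 24 CPM (log2 1.26, SE 0.06), and Arc from 47.2 ± 8.48 to 159 ± 84.7 CPM (log2 1.75, SE 0.34). Of 16339 genes tested, 393 passed in edgeR, 314 higher (79.9%) and 79 lower, and 64 changed more than 1.5-fold. With upper-quartile scaling 358 passed, 67.0% of them higher.

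Of 40 immediate early genes, 22 rose in cKO mice after novelty, and 30 rose adjusted over the list alone. Its median was 0.71 (camera adjusted p = 1.05e-37, adjusted p = 0.0469 with an estimated correlation). Fosb rose by 2.78 on the log2 scale (SE 0.13), Egr4 by 2.11 (SE 0.28), Egr1 by 1.83 (SE 0.13), Junb by 1.54 (SE 0.37) and Nr4a1 by 1.35 (SE 0.18). Of 15 glucocorticoid-responsive genes 7 rose, among them Per1 (0.88, SE 0.12), Cdkn1a (0.85, SE 0.14), Errfi1 (0.79, SE 0.10) and Tsc22d3 (0.72, SE 0.11), and 10 rose adjusted over the list alone. Its median was 0.49 (camera adjusted p = 2.11e-11, adjusted p = 0.0572 with an estimated correlation). Of 18 circadian clock genes 4 rose, Per1, Nfil3 (0.79, SE 0.19), Per2 (0.67, SE 0.11) and Bhlhe40 (0.46, SE 0.05), and 5 rose adjusted over the list alone. Its median was 0.07 (camera adjusted p = 0.000997, adjusted p = 0.386 with an estimated correlation). Of 24 heat shock and unfolded protein response genes 4 rose, Dnajb1 (0.61, SE 0.05), Hspa5 (0.41, SE 0.05), Xbp1 (0.34, SE 0.03) and Hsph1 (0.22, SE 0.05), and 14 rose adjusted over the list alone. Its median was 0.17 (camera adjusted p = 1.63e-10, adjusted p = 0.0463 with an estimated correlation).

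Of 18 p53 and DNA damage response genes, Cdkn1a and Mdm2 (0.25, SE 0.04) rose in cKO mice after novelty, and 6 rose adjusted over the list alone. Its median was 0.07 (camera adjusted p = 0.031, adjusted p = 0.205 with an estimated correlation). Of 23 cholesterol synthesis genes 2 rose, among them Cyp51 (0.41, SE 0.05), and 5 rose adjusted over the list alone. Its median was 0.10 (camera adjusted p = 4.38e-05, adjusted p = 0.668 with an estimated correlation). A further 4 lists passed without any member passing over all genes. MHC class I and interferon-stimulated genes had a median of -0.13 (camera adjusted p = 0.00306, adjusted p = 0.563 with an estimated correlation). Nuclear-encoded respiratory chain genes had -0.07 (camera adjusted p = 0.00065, adjusted p = 0.957 with an estimated correlation) and oligodendrocyte markers -0.11 (camera adjusted p = 0.0134, adjusted p = 0.957 with an estimated correlation). The 4 measured sex-linked transcripts had a median of 0.10, and 3 rose adjusted over the list alone (camera adjusted p = 0.00658, adjusted p = 0.164 with an estimated correlation). Among them was Eif2s3y (0.30, SE 0.08), which missed the threshold over all genes (edgeR adjusted p = 0.0789).

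Single genes of other lists changed in cKO mice after novelty as well. The SAGA subunit gene Atxn7 (0.39, SE 0.05), the cAMP-responsive repressor gene Crem (0.36, SE 0.06), the muscarinic receptor gene Chrm4 (0.57, SE 0.10), the ribosomal protein gene Rpl24 (0.28, SE 0.03) and Stat3 (0.16, SE 0.04), a neighbour of Kat2a, rose. Decreases were found in Col22a1 (-0.66, SE 0.14), Plekho2 (-0.58, SE 0.06), Gas1 (-0.49, SE 0.07), the microglial purinergic receptor gene P2ry13 (-0.47, SE 0.06), the potassium channel gene Kcna4 (-0.39, SE 0.05) and Tab1 (-0.36, SE 0.05). Of the 33 named genes that passed, 28 passed in every edgeR fit that left out 1 library, whereas Arc and Hsph1 passed in 9 of 13, Stat3 in 4, Nfil3 in 3 and Junb in 1. The p53 list passed camera in 9 and the oligodendrocyte list in 11 of these 13 fits. The count of 393 genes fell to 238 without cKO naive library 2, and DESeq2 called 639.

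Averaged over both genotypes in 24 libraries, 1097 of 16744 genes passed in edgeR, 741 higher (67.5%) and 356 lower, with 53.9% higher under upper-quartile scaling. Egr2 (4.39, SE 0.23), Homer1 (1.16, SE 0.05), Per1 (0.93, SE 0.08) and Cdkn1a (0.91, SE 0.12) rose. Immediate early genes had 29 of 40 members higher (35 adjusted over the list alone) and glucocorticoid-responsive genes 10 of 15 (11 adjusted over the list alone). Heat shock and unfolded protein response genes had 12 of 24 higher (14 adjusted over the list alone) and p53 response genes 6 of 18 (8 adjusted over the list alone). These 4 lists passed camera at adjusted p of 8.58e-54, 3.95e-18, 1.69e-11 and 0.00045, and also with an estimated correlation, at adjusted p of 0.00138, 0.00233, 0.00414 and 0.00414. Circadian clock genes (5 higher, 7 adjusted over the list alone, camera adjusted p = 2.35e-06) had adjusted p = 0.0592 with an estimated correlation. Cholesterol synthesis genes (6 higher, among them Idi1 at 0.27, SE 0.06, and 7 adjusted over the list alone, camera adjusted p = 1.04e-05) had adjusted p = 0.539 with an estimated correlation. MHC class I and interferon-stimulated genes had a median of -0.09 (camera adjusted p = 0.0216, adjusted p = 0.559 with an estimated correlation).

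Smaller changes in the novelty average were found in single genes. Neither the SAGA and ATAC list nor the microglia list passed camera there. Atxn7 (0.33, SE 0.04), Taf12 (0.14, SE 0.04), the acetyltransferase gene Ep300 (0.12, SE 0.03), Stat3 (0.15, SE 0.03) and the chaperone gene Hsph1 (0.20, SE 0.04) rose, and 2 of 27 SAGA and ATAC subunits passed (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.16). The microglial gene Tmem119 rose (0.14, SE 0.04), whereas P2ry12, another microglial gene, fell (-0.16, SE 0.05). Tnfsf10 (-0.67, SE 0.14), the potassium channel gene Kcnj2 (-0.55, SE 0.16) and the oligodendrocyte gene Opalin (-0.28, SE 0.08) also fell. Kat2a had a log2 fold change of -0.06 (SE 0.04, edgeR adjusted p = 0.439). Of the 15 named genes that passed, 10 passed in every edgeR fit that left out 1 library, whereas Taf12 passed in 23 of 24, Tmem119 in 12, P2ry12 in 11, Kcnj2 in 6 and Opalin in 5.

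The interaction asked whether the novelty response differed between genotypes, and no gene passed. Of 16744 genes tested edgeR called 0, with 688 at an unadjusted p below 0.05, DESeq2 called 0 with 792 and limma-voom 0 with 740. The smallest p in edgeR belonged to Gm15478, a transcript annotated as antisense with at most 0.918 CPM in a group mean, whose log2 fold changes differed by 1.56 (SE 0.36). Next came the lipase gene Pla2g7 (-0.34, SE 0.08) and the methylmalonyl-CoA mutase gene Mut (0.51, SE 0.12). The edgeR adjusted p of each was 1. Pla2g7 averaged 165 and 183 CPM in naive and novelty controls and 167 and 148 CPM in naive and novelty cKO mice. When the interaction was adjusted over only the 196 genes called for novelty in controls, the smallest edgeR adjusted p was 0.109, and over the 393 called in cKO mice it was 0.0821. The log2 fold changes of novelty in both genotypes, which share no library, correlated across 16023 genes (Pearson r = 0.371, Spearman rho = 0.293), where genes are not independent replicates. Of the genes called, 110 rose in both genotypes against 3.19 for independent lists, 6 fell in both against 0.16, and 0 went in opposite directions in edgeR calls.

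For the interaction 6 lists passed camera, all with an adjusted p of 0.774 with an estimated correlation and without any member passing over all genes. The median difference was -0.06 for the nuclear-encoded respiratory chain (camera adjusted p = 0.0126), -0.07 for cytosolic ribosomal proteins, 0.13 for sex-linked transcripts, -0.26 for dentate granule neuron markers, -0.16 for oligodendrocyte markers and -0.61 for blood markers (camera adjusted p = 0.0226 for each). Left-out libraries ended these calls. No list passed without cKO novelty library 1, 1 passed without control novelty library 3, and 3 passed without control naive library 2, control novelty library 4 or cKO naive library 2.

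The next comparison asked which genes depend on Kat2a in naive mice, in 6 cKO against 6 control libraries. Besides Kat2a, the largest decreases among named genes were in Oxr1, a gene of oxidation resistance, from 389 ± 12.8 to 181 ± 34 CPM (log2 -1.10, SE 0.10), Grem1, a BMP antagonist gene, from 11.1 to 6.06 CPM (log2 -0.86, SE 0.11), and Penk, which encodes proenkephalin, from 27.4 ± 3.25 to 15.6 ± 2.61 CPM (log2 -0.81, SE 0.11). The cadherin-related gene Cdhr1 rose from 8.78 to 20.2 CPM (log2 1.22, SE 0.14) and Baiap3 from 12.1 to 24.7 CPM (log2 1.02, SE 0.16). Oxr1 (ENSMUSG00000022307) lies on GRCm38 chromosome 15 at 41447482 to 41861048, Grem1 on chromosome 2 at 113746164 to 113758646 and Penk (ENSMUSG00000045573) on chromosome 4 at 4133531 to 4138819. Of 16360 genes tested, 131 passed in edgeR, 50 higher and 81 lower, and 24 changed more than 1.5-fold.

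Further decreases in naive cKO mice were in the retinoic acid hydroxylase gene Cyp26b1 (-0.76, SE 0.16), the orexin receptor gene Hcrtr2 (-0.57, SE 0.12), the serotonin receptor genes Htr2c (-0.53, SE 0.10) and Htr2a (-0.43, SE 0.09), and Fosl2 (-0.51, SE 0.11) and Bhlhe40 (-0.28, SE 0.06), which rose with novelty. Further increases were in the chloride channel gene Ano2 (1.22, SE 0.21), Cpxm2 (0.86, SE 0.17) and the erythropoietin receptor gene Epor (0.72, SE 0.10). Of 22 glutamate receptor genes Gria3 (-0.30, SE 0.05) and Grm5 (-0.20, SE 0.04) fell, and 5 fell adjusted over the list alone. Its median was -0.12 (camera adjusted p = 0.00102, adjusted p = 0.0779 with an estimated correlation). Of 15 GABA receptor genes Gabrb2 (-0.20, SE 0.04) fell, and 4 fell adjusted over the list alone. Its median was -0.15 (camera adjusted p = 0.000462, adjusted p = 0.196 with an estimated correlation). Of 53 monoamine, acetylcholine and peptide receptor genes 2 fell, Htr2c and Htr2a, and 3 fell adjusted over the list alone. Its median was -0.04 (camera adjusted p = 0.0402, adjusted p = 0.39 with an estimated correlation).

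Of 45 synaptic vesicle and postsynaptic scaffold genes Vamp2 (-0.19, SE 0.04) fell in naive cKO mice, and adjusted over the list alone 1 rose and 3 fell, with a median of -0.04 (camera adjusted p = 0.0099, adjusted p = 0.36 with an estimated correlation). Of 44 cAMP, calcium and MAP kinase genes the kinase gene Mapk3 (0.31, SE 0.05) rose, and adjusted over the list alone 1 rose and 1 fell, while the list median was -0.04 (camera adjusted p = 0.0425, adjusted p = 0.3 with an estimated correlation). The sodium channel subunit gene Scn3b fell (-0.44, SE 0.09), but the 44 voltage-gated ion channel genes did not pass (median -0.02, camera adjusted p = 0.0968). Of 55 cytosolic ribosomal protein genes 4 fell, among them Rpl23 (-0.37, SE 0.06) and Rpl15 (-0.36, SE 0.06), and 11 fell adjusted over the list alone. Its median was -0.13 (camera adjusted p = 2.57e-06, adjusted p = 0.444 with an estimated correlation). NF-kappa-B pathway genes had a median of 0.09 (camera adjusted p = 0.00293, adjusted p = 0.196 with an estimated correlation). MHC class I and interferon-stimulated genes had a median of 0.10 (camera adjusted p = 0.00157, adjusted p = 0.263 with an estimated correlation). Neither had a member that passed over all genes or adjusted over the list alone.

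Several lists of cell type markers passed camera at the preset correlation in naive cKO mice, and none passed with an estimated correlation. In the exact permutation test of list levels, chosen after seeing the data, the p adjusted over the lists ran from 0.0972 to 0.402 for them. All 14 oligodendrocyte markers had lower levels, Ugt8a (-0.39, SE 0.08) passed and 10 fell adjusted over the list alone. Its median was -0.22 (camera adjusted p = 1.21e-08, adjusted p = 0.196 with an estimated correlation). Of 12 CA1 pyramidal neuron markers Pex5l (-0.27, SE 0.04) fell, and 5 fell adjusted over the list alone. Its median was -0.22 (camera adjusted p = 0.000193, adjusted p = 0.196 with an estimated correlation). Of 8 subiculum markers Ndst4 (-0.40, SE 0.09) fell, and 3 fell adjusted over the list alone. Its median was -0.34 (camera adjusted p = 0.000326, adjusted p = 0.196 with an estimated correlation). Of 12 neocortex markers Calb1 (-0.35, SE 0.06), which CA1 and dentate neurons also express, fell, and 2 fell adjusted over the list alone. Its median was -0.10 (camera adjusted p = 0.00316, adjusted p = 0.196 with an estimated correlation). Interneuron markers passed with a median of -0.09 and 2 lower adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.196 with an estimated correlation). Endothelium and pericyte markers passed with a median of -0.13 and 2 lower adjusted over the list alone (camera adjusted p = 0.000754, adjusted p = 0.368 with an estimated correlation). Blood markers had a median of 0.64, and 2 of 5 rose adjusted over the list alone (camera adjusted p = 0.0425, adjusted p = 0.502 with an estimated correlation).

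Counts of the naive genotype comparison moved with single libraries. Without control naive libraries 2 and 4, the shallowest and the one with the most choroid plexus transcripts, a fit chosen after seeing the data, 33 genes passed, 31 of them among the 131. Counts fell to 40 without control naive library 6, 55 without control naive 5, 80 without control naive 4, 47 without cKO naive 2, 58 without cKO naive 1, 59 without cKO naive 6 and 80 without cKO naive 5, whereas DESeq2 called 457. Of the 27 named genes 12 passed in every edgeR fit that left out 1 library. Of 12 such fits, Gria3 passed in 11, Calb1 in 9, Cpxm2 in 7, Vamp2 in 5, Cyp26b1, Htr2c, Scn3b and Ndst4 in 4, Bhlhe40 in 3, Fosl2 and Htr2a in 2, and Hcrtr2, Grm5, Gabrb2 and Ugt8a in 1. The monoamine receptor and blood lists passed camera in 6 and the cAMP list in 4 of them.

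After novelty, the comparison of 7 cKO with 5 control libraries asked the same of the stimulated state. Oxr1 was 380 ± 55.8 CPM in control and 178 ± 25.1 CPM in cKO mice (log2 -1.09, SE 0.10), and Penk 29.3 ± 4.18 and 15.1 ± 0.942 CPM (log2 -0.96, SE 0.08). Grem1 (-1.04, SE 0.16), Cyp26b1 (-0.80, SE 0.19), the neuropeptide gene Adcyap1 (-0.75, SE 0.20), Lefty1 (-0.69, SE 0.15) and the serotonin receptor gene Htr1b (-0.66, SE 0.16) fell. Baiap3 rose from 9.04 to 24.4 CPM (log2 1.46, SE 0.13), and Cldn26 (1.62, SE 0.34), the p53 family gene Trp73 (1.23, SE 0.21), Cdhr1 (1.08, SE 0.13), Olfm4 (1.03, SE 0.24), the collagen gene Col6a2 (1.0, SE 0.13), Otof (1.0, SE 0.16) and Ano2 (0.94, SE 0.15) rose. Of 16188 genes tested, 733 passed in edgeR, 344 higher and 389 lower, and 113 changed more than 1.5-fold. The balance turned with upper-quartile scaling (388 higher, 322 lower), at an adjusted p below 0.1 (686 and 662) and without control novelty library 4 (537 and 408). With the trend with GC content removed, a setting chosen after seeing the data, 910 passed, 34.2% of them higher against 46.9%.

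Of 55 cytosolic ribosomal protein genes 18 fell in novelty-exposed cKO mice, among them Rps3 (-0.38, SE 0.06) and Rpl32 (-0.36, SE 0.05), and 22 fell adjusted over the list alone. Its median was -0.18 (camera adjusted p = 1.57e-12, adjusted p = 0.345 with an estimated correlation). Of 45 synaptic genes 9 fell and 1 rose, with Camk2a, an abundant calcium-dependent kinase gene, falling from 4270 to 3500 CPM (log2 -0.28, SE 0.06), the inhibitory synapse adhesion gene Nlgn2 lower (-0.16, SE 0.03) and the release site gene Rims1 higher (0.30, SE 0.06). Adjusted over the list alone 12 fell and 2 rose, with a median of -0.07 (camera adjusted p = 0.000382, adjusted p = 0.317 with an estimated correlation). Of 44 cAMP, calcium and MAP kinase genes 9 fell and 1 rose, with the adenylyl cyclase gene Adcy1 (-0.38, SE 0.08) and the calmodulin gene Calm3 (-0.24, SE 0.04) lower and Mapk3 (0.30, SE 0.05) higher. Adjusted over the list alone 10 fell and 2 rose, with a median of -0.06 (camera adjusted p = 0.00279, adjusted p = 0.345 with an estimated correlation). Of 44 voltage-gated ion channel genes 6 fell, among them Scn4b (-0.61, SE 0.13), Scn3b (-0.55, SE 0.07) and Hcn2 (-0.19, SE 0.04), and adjusted over the list alone 7 fell and 2 rose, with a median of -0.07 (camera adjusted p = 0.0253, adjusted p = 0.345 with an estimated correlation).

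Of 15 GABA receptor genes 3 fell in novelty-exposed cKO mice, among them Gabra5 (-0.30, SE 0.06) and Gabrb2 (-0.27, SE 0.05), the same number adjusted over the list alone. Its median was -0.10 (camera adjusted p = 0.00102, adjusted p = 0.345 with an estimated correlation). Of 22 glutamate receptor genes 2 fell, among them Gria3 (-0.27, SE 0.05), and 3 fell adjusted over the list alone. Its median was -0.10 (camera adjusted p = 0.0319, adjusted p = 0.345 with an estimated correlation). Monoamine, acetylcholine and peptide receptors went both ways, with 3 higher and 5 lower, and 6 higher and 7 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.202). Htr1a and Htr2a fell (-0.55, SE 0.06 and 0.08), whereas Tacr1, the substance P receptor gene (0.68, SE 0.15), and the somatostatin receptor gene Sstr3 (0.36, SE 0.07) rose. Nuclear-encoded respiratory chain genes had a median of -0.08 without a member that passed (camera adjusted p = 1.3e-05, adjusted p = 0.523 with an estimated correlation). Of 30 NF-kappa-B pathway genes Traf3 (0.20, SE 0.04) rose, and 3 rose adjusted over the list alone. Its median was 0.07 (camera adjusted p = 0.0324, adjusted p = 0.523 with an estimated correlation). Of 27 SAGA and ATAC subunits 3 rose, among them Yeats2 (0.23, SE 0.06) and Atxn7 (0.20, SE 0.05), and 2 fell, Kat2a and Sf3b3 (adjusted over the list alone 3 higher and 3 lower, camera adjusted p = 0.698).

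Several lists of cell type markers again passed camera at the preset correlation, and none passed with an estimated correlation. All 14 oligodendrocyte markers had lower levels in novelty-exposed cKO mice, Gjc3 (-0.39, SE 0.10) passed and 8 fell adjusted over the list alone. Its median was -0.35 (camera adjusted p = 3.68e-08, adjusted p = 0.373 with an estimated correlation). Of 12 CA1 pyramidal neuron markers 4 fell, among them Fam84a (-0.43, SE 0.07), Wfs1 (-0.38, SE 0.09) and Pex5l (-0.36, SE 0.07), and 8 fell adjusted over the list alone. Its median was -0.25 (camera adjusted p = 7.51e-06, adjusted p = 0.317 with an estimated correlation). Of 12 neocortex markers Lamp5 (-0.50, SE 0.09) and Etv1 (-0.38, SE 0.09), also a subiculum marker, fell, and 4 fell adjusted over the list alone. Its median was -0.10 (camera adjusted p = 0.0253, adjusted p = 0.345 with an estimated correlation). Of 17 endothelium and pericyte markers Ly6c1 (-0.36, SE 0.07) fell, the same number adjusted over the list alone. Its median was -0.13 (camera adjusted p = 0.0073, adjusted p = 0.523 with an estimated correlation). Dentate granule neuron markers had a median of -0.30, with C1ql2 at -1.15 (SE 0.31, edgeR adjusted p = 0.065) and 2 lower adjusted over the list alone (camera adjusted p = 0.00279, adjusted p = 0.631 with an estimated correlation). Oligodendrocyte precursor markers had a median of -0.14 and 4 lower adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.373 with an estimated correlation).

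The exact permutation test of list levels over the libraries, chosen after seeing the data, gave differences after novelty of -0.25 for CA1 markers (exact p = 0.00126, adjusted over the lists 0.0454), -0.06 for voltage-gated ion channels (exact p = 0.00253, adjusted 0.0455) and -0.07 for synaptic genes (exact p = 0.00379, adjusted 0.0455). In naive mice glutamate receptors differed by -0.10 at the smallest p that 6 against 6 libraries allow (exact p = 0.00216, adjusted 0.0778), at which a list cannot pass alone among 36. Cytosolic ribosomal proteins did not pass this test. They differed by -0.14 in naive mice (exact p = 0.147, adjusted 0.311) and by -0.16 after novelty (exact p = 0.0189, adjusted 0.086). The count of 733 genes in novelty-exposed mice was 324 without control novelty library 2, 364 without control novelty 5, 473 without control novelty 3, 430 without cKO novelty 5 and 484 without cKO novelty 7, and 1155 in DESeq2. Of the 45 named genes 30 passed in every edgeR fit that left out 1 library. Of 12 such fits, Lefty1, Cldn26, Hcn2 and Camk2a passed in 11, Scn4b in 10, Olfm4 in 9, Htr1b in 8, Cyp26b1 and Wfs1 in 5, Adcyap1 and Gjc3 in 4, Yeats2 and Sf3b3 in 3, and Atxn7 and Etv1 in 2. In the same fits camera passed in 6 for precursor markers, 8 for NF-kappa-B, 9 for glutamate receptors and for voltage-gated channels, 10 for neocortex, and 11 for dentate and for endothelium markers.

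**Figure D3:**
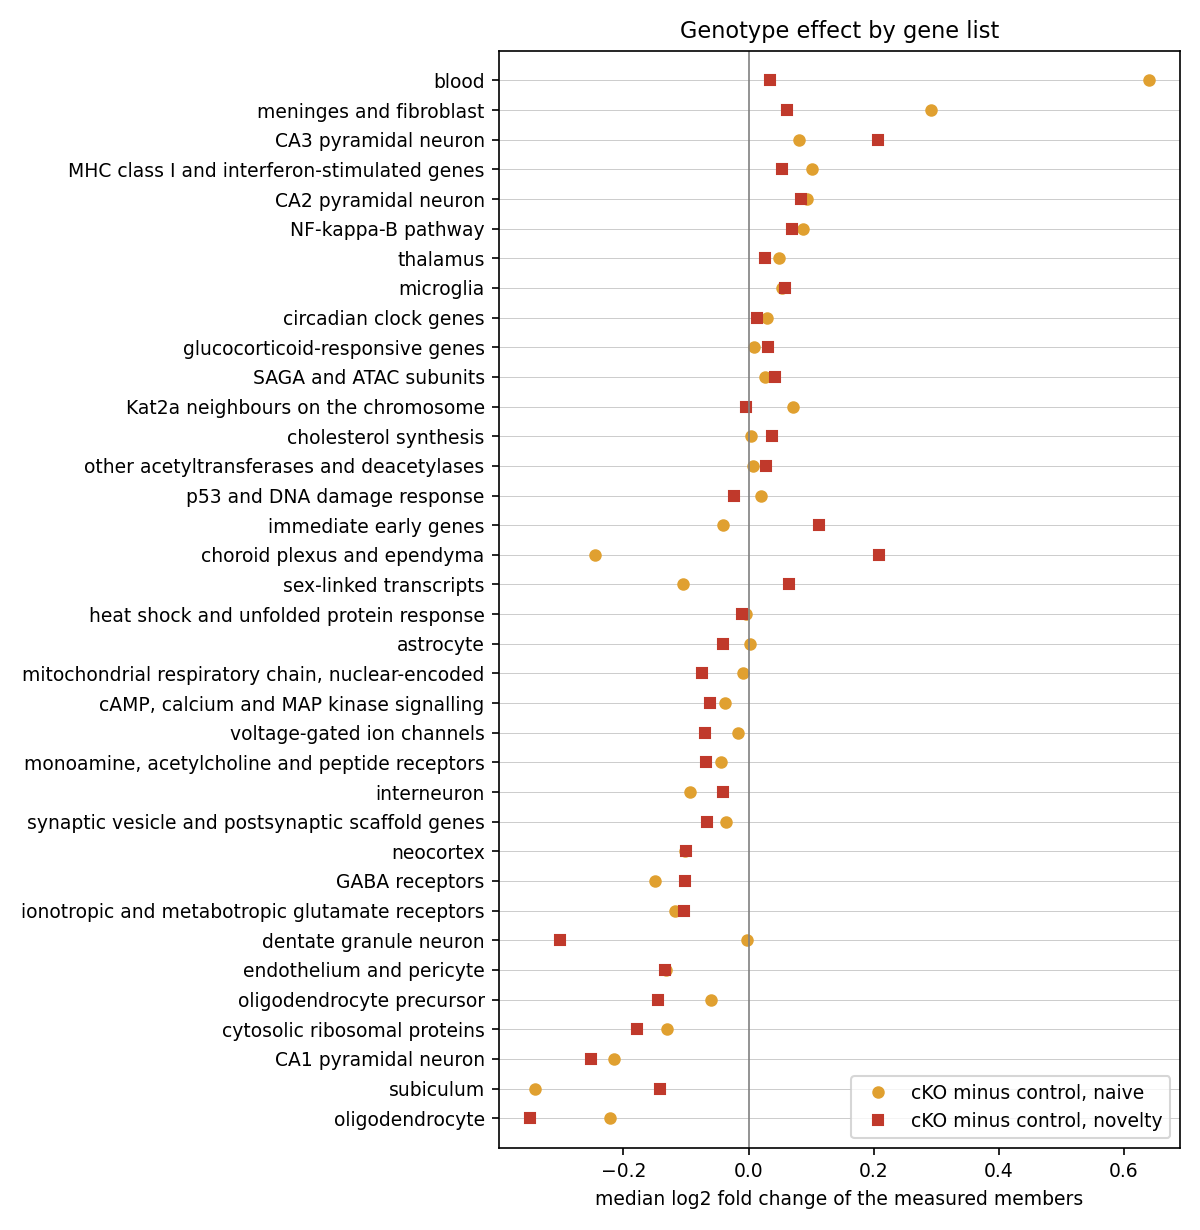
Median log2 fold change, cKO against control (horizontal axis), of the measured members of each of the 36 lists (vertical axis), with circles for naive and squares for novelty-exposed mice. Oligodendrocyte markers lie at -0.22 and -0.35 and CA1 pyramidal neuron markers at -0.22 and -0.25.

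Averaged over exposures in all 24 libraries, 2017 of 16744 genes passed in edgeR, 958 higher (47.5%) and 1059 lower. The balance turned with upper-quartile scaling (58.5% higher), with a mean of at least 10 reads (1014 higher, 1005 lower) and without cKO novelty library 3 (1144 and 1066). Oxr1 (-1.10, SE 0.08), Grem1 (-0.95, SE 0.10), Penk (-0.89, SE 0.07), C1ql2 (-0.86, SE 0.23), Kat2a (-0.79, SE 0.04, edgeR adjusted p = 9.08e-14) and the neuropeptide receptor gene Npbwr1 (-0.69, SE 0.13) fell most among named genes, and Baiap3 (1.24, SE 0.11), Cdhr1 (1.15, SE 0.10), Mfap4 (0.77, SE 0.17) and Rreb1 (0.75, SE 0.17) rose. The median size of a called change was 0.19 on the log2 scale, and 146 genes changed more than 1.5-fold. The 2 genotype comparisons, which share no library, had log2 fold changes that correlated across 16095 genes (Pearson r = 0.439, Spearman rho = 0.467). Of their calls 28 rose in both against 1.04 for independent lists, 58 fell in both against 1.96, and 0 went in opposite directions in edgeR calls. Of the 729 genes called after novelty and tested in both, 702 (96.3%) had the same sign in naive mice.

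In the genotype average, 20 of 55 ribosomal protein genes fell, among them Rpl15 (-0.35, SE 0.04; 24 lower adjusted over the list alone; camera adjusted p = 1.45e-11, adjusted p = 0.203 with an estimated correlation). Of 22 glutamate receptor genes 5 fell, among them Gria3 (-0.29, SE 0.04), and adjusted over the list alone 7 fell and 2 rose (median -0.12, camera adjusted p = 0.00155, adjusted p = 0.0293 with an estimated correlation). Of 15 GABA receptor genes 6 fell, among them Gabrb2 (-0.24, SE 0.04), and 9 fell adjusted over the list alone (camera adjusted p = 0.000101, adjusted p = 0.165 with an estimated correlation). Of 54 monoamine, acetylcholine and peptide receptors 7 fell, among them Htr1a (-0.44, SE 0.05), and 5 rose (10 lower and 7 higher adjusted over the list alone, camera adjusted p = 0.0464, adjusted p = 0.315 with an estimated correlation). Of 44 voltage-gated channel genes 8 fell, among them Scn3b (-0.50, SE 0.06), and 2 rose (12 lower and 5 higher adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.246 with an estimated correlation). Of 45 synaptic genes 11 fell, among them Vamp2 (-0.17, SE 0.03), and 1 rose (17 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.000328, adjusted p = 0.165 with an estimated correlation). Of 44 cAMP, calcium and MAP kinase genes 14 fell and Mapk3 rose (0.30, SE 0.03; 17 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00236, adjusted p = 0.197 with an estimated correlation). Of 53 respiratory chain genes 4 fell, and 1 adjusted over the list alone (median -0.05, camera adjusted p = 0.00155, adjusted p = 0.751 with an estimated correlation).

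Of 30 NF-kappa-B pathway genes 3 rose in the genotype average, among them Relb (0.23, SE 0.06), the same number adjusted over the list alone (median 0.07, camera adjusted p = 0.00241, adjusted p = 0.197 with an estimated correlation). Of 29 MHC class I and interferon-stimulated genes 3 rose, among them Irf1 (0.38, SE 0.10) and the peptide-loading gene Tapbp (0.21, SE 0.04), the same number adjusted over the list alone (median 0.10, camera adjusted p = 0.0371, adjusted p = 0.445 with an estimated correlation). Of 27 SAGA and ATAC subunits 4 fell, Kat2a, Sf3b3 (-0.17, SE 0.03), Tada1 (-0.12, SE 0.03) and Atxn7l3, and 2 rose, Taf6l (0.20, SE 0.05) and Atxn7 (adjusted over the list alone 5 lower and 5 higher, median 0.03, mean -0.01, camera adjusted p = 0.964 towards lower). Atxn7l3 and Atxn7 were named after their values were seen. Of 26 other acetyltransferases and deacetylases 3 rose, among them Hdac4 (0.16, SE 0.04), and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.57). Of 10 neighbours of Kat2a on the chromosome Cnp fell (-0.21, SE 0.06), a myelin gene (median 0.03, camera adjusted p = 0.663).

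Oligodendrocyte markers were lower beside all of these groups in the genotype average, with 11 of 14 called, among them Ugt8a and Mal (-0.32, SE 0.07), and all 14 lower adjusted over the list alone (median -0.31, camera adjusted p = 4.95e-10, adjusted p = 0.197 with an estimated correlation). The cKO libraries numbered 4 stood apart, with mean oligodendrocyte marker levels of 7.09 (naive) and 7.17 log2 CPM (novelty). The other cKO libraries lay between 6.31 and 6.79, naive controls between 6.96 and 7.05 and novelty controls between 6.80 and 7.14. Of 12 CA1 pyramidal neuron markers 6 fell, among them Pex5l (-0.32, SE 0.04), and 8 adjusted over the list alone (median -0.22, camera adjusted p = 4.29e-06, adjusted p = 0.0982 with an estimated correlation). Of 17 dentate granule neuron markers 3 fell, C1ql2, Stxbp6 and Trpc6, and adjusted over the list alone 3 fell and 1 rose (camera adjusted p = 0.0312, adjusted p = 0.751 with an estimated correlation). Subiculum markers fell in 3 of 8 genes and in 4 adjusted over the list alone (camera adjusted p = 0.00236, adjusted p = 0.197 with an estimated correlation). Interneuron markers fell in 3 of 16 genes and in 5 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.278 with an estimated correlation). Oligodendrocyte precursor markers fell in 2 of 8 genes and in 5 adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.278 with an estimated correlation). Endothelium and pericyte markers fell in 2 of 17 genes, also 2 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.324 with an estimated correlation). Neocortex markers fell in 3 of 12 genes and in 4 adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.165 with an estimated correlation). Of the 34 named genes that passed, 30 passed in every edgeR fit that left out 1 library, whereas Stxbp6 passed in 23 of 24, Atxn7 in 13, Cnp in 9 and Trpc6 in 8. Camera passed in 12 of these 24 fits for monoamine receptors, in 16 for MHC genes and for dentate markers, and in 23 for voltage-gated channels and for precursor markers.

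The other lists did not pass in the genotype average. Immediate early genes had a median of 0.00 with 1 member higher and 3 lower (camera adjusted p = 0.94), glucocorticoid-responsive genes 0.03 (1 higher, 1 lower; adjusted p = 0.94) and circadian clock genes 0.05 (2 higher, 1 lower; adjusted p = 0.964). Heat shock and unfolded protein response genes had a median of -0.01, with 5 lower, among them Atf4 (-0.19, SE 0.04; camera adjusted p = 0.295), and p53 response genes 0.01, with 3 lower, among them Zmat3 (-0.19, SE 0.03; camera adjusted p = 0.52). Cholesterol synthesis genes (median 0.03, camera adjusted p = 0.641) and sex-linked transcripts (0.00, camera adjusted p = 0.94) had no member that passed. Among markers the medians were 0.09 for CA2 neurons (camera adjusted p = 0.319), 0.14 for CA3 neurons (0.785), -0.02 for astrocytes (0.641), 0.05 for microglia (0.13), 0.00 for choroid plexus and ependyma (0.408), 0.06 for thalamus (0.927), 0.19 for meninges and fibroblasts (0.275) and 0.25 for blood (0.465). Among lists that passed, median, mean and test had the same sign in every comparison. For some that did not pass they differed, such as choroid plexus markers after novelty (median 0.21, mean 0.13, camera towards lower at adjusted p = 0.838). With an estimated correlation, camera calls held for the immediate early, glucocorticoid, circadian and p53 lists in controls after novelty and the immediate early and heat shock lists in cKO mice. They also held for 4 lists in the novelty average and the glutamate receptors in the genotype average, and for no other.

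In the authors' deposited tables, made with DESeq2, 447 genes had an adjusted p below 0.05 for novelty in controls, 715 for novelty in cKO mice, 515 for genotype in naive mice and 1312 for genotype after novelty. All 195 edgeR calls for novelty in controls that the authors' deposited table lists are among its calls, as are all 393 for novelty in cKO mice, all 131 for genotype in naive mice and 729 of 730 for genotype after novelty. Across genes the log2 fold changes of the authors' deposited tables and of edgeR correlated with r between 0.97 and 0.985.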

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

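The tests of a lost or foreign segment around Oxr1, of list levels and of a change of few myelin genes alone were chosen only after the result was seen. The removal of the GC trend and the dentate marker covariate, used below, were chosen after the data had been seen.

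Oxr1 was lower in both cKO groups (-1.10, SE 0.08, in the genotype average), by more than Kat2a itself, and lies on another chromosome. The tables argue against the loss of a wide segment, since the 35 other tested genes within 5 Mb had a median log2 fold change of -0.055. A segment carried over from another strain stays open. Of these 35 neighbours 8 passed, 22.9% against 12.3% of genes elsewhere (Fisher's exact test, p = 0.0681), which decides nothing. That Oxr1 may depend on Kat2a, and that the Cre transgene may have inserted in or near Oxr1, were not tested.

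Fold changes of the genotype average rose with GC content of the gene (Spearman rho = 0.247 across genes, 0.265 in naive mice and 0.181 after novelty), and control naive library 2 had a GC slope of -0.263 log2 per 10% GC, outside the range of -0.052 to 0.102 of all other libraries. GC bias as the whole cause of the calls is argued against, since 85.4% of the 2017 calls passed again with each library's GC trend removed. Dentate tissue carried into some samples is argued against as the whole cause in the genotype average, with 89.6% called again beside the dentate marker level as a covariate. For genotype after novelty only 470 of the 733 calls (64.1%) passed again, so dentate tissue stays open there. Whether the GC slope differs between genotypes stays open, at a difference of 0.048 and a permutation p of 0.121. A dependence of the genes on Kat2a may account for what remains, as a hypothesis that was not tested. Only cKO mice carried the Cre transgene, so its effects cannot be told apart from those of Kat2a loss. A difference in the tissue composition of the samples also stays open.

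Oligodendrocyte markers were lower in cKO mice, with 14 of 14 below control in the genotype average (camera adjusted p = 4.95e-10, adjusted p = 0.197 with an estimated correlation), so that a change of a few myelin genes alone is argued against. GC bias is argued against too, as their median was -0.301 with the GC trend removed and -0.313 without. Fewer oligodendrocytes or less white matter in the dissected cKO samples may account for it. Of the 100 other genes that followed the marker level most closely between libraries of a group 95% had a negative fold change, against 49.6% of other genes. Their median was -0.17, and 32 were called lower, whereas Rapgef4 (0.20) and Bag2 (0.27), named after their values were seen, were called higher. These genes were picked for following the markers, so the test cannot tell fewer cells from a joint fall of oligodendrocyte transcripts. Whether fewer such cells would come from dissection or from the mice was not tested. The exact permutation test of the list level, chosen after seeing the data, did not pass over the lists in naive mice (exact p = 0.0152, adjusted 0.0972) or after novelty (exact p = 0.0177, adjusted 0.086).

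Single libraries that lay far from the rest of their group were looked for in 696 groups of values, of which 40 held one, where chance gives about 1 in 20, or 34.8. Of these, 7 fell on control naive library 2 and 5 on cKO novelty library 4. Control naive library 2 was high for Homer1 (157 CPM, others 122 to 131), Rpl24 (85.0, others 68.8 to 72.8), Rpl15 (80.8, others 59.8 to 65.9), Grm5 (463, others 405 to 423) and Vamp2 (1120, others 991 to 1010). It was low for Atxn7l3 (218, others 239 to 249) and for the mean level of the Kat2a neighbours, 3.87 log2 CPM against 4.08 to 4.16. cKO novelty library 4 was high for Mal (227 CPM, others 138 to 152), Cnp (348, others 205 to 254), Opalin (27.4, others 14.6 to 18.5) and Klhdc9 (5.5, others 2.86 to 4.0), and for oligodendrocyte markers (7.17 log2 CPM, others 6.31 to 6.62).

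In control naive mice, library 4 stood apart for Fos (5.78 CPM) and for MHC class I and interferon-stimulated genes (2.48 log2 CPM), library 3 for Xbp1 (62.2 CPM) and Ndst4 (41.4 CPM), library 1 for Rreb1 (75.1 CPM) and library 5 for glutamate receptors (6.58 log2 CPM). In control novelty mice, library 1 stood apart for Penk (36.6 CPM), Calb1 (187 CPM) and circadian clock genes (5.73 log2 CPM), library 2 for Cdhr1 (10.9 CPM), library 3 for Oxr1 (476 CPM, others 343 to 379) and library 4 for Tacr1 (1.23 CPM) and Nlgn2 (253 CPM). In cKO naive mice, library 1 stood apart for Tsc22d3 (44.2 CPM) and Hcn2 (57.7 CPM), library 2 for Grem1 (4.84 CPM), library 3 for Cpxm2 (7.89 CPM) and Lamp5 (55.6 CPM), library 4 for oligodendrocyte markers (7.09 log2 CPM, others 6.62 to 6.79) and library 5 for Fam84a (91.9 CPM) and Idi1 (7.39 CPM). In cKO novelty mice, library 1 stood apart for Grm5 (424 CPM), library 2 for synaptic genes (7.95 log2 CPM) and Atxn7l3 (199 CPM), library 3 for Yeats2 (39.9 CPM), library 6 for Hspa5 (308 CPM) and Crem (25.7 CPM), and library 7 for the share of reads in its 10 leading genes (3.12%, others 2.76 to 2.89%).

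The novelty response differed between genotypes for 6 lists in the camera test of the interaction, with median differences of -0.056 (respiratory chain), -0.07 (ribosomal proteins), 0.131 (sex-linked transcripts), -0.259 (dentate granule neuron), -0.158 (oligodendrocyte) and -0.609 (blood). None of them passed with an estimated correlation (adjusted p = 0.774 for each), and chance cannot be excluded for their number, since 65 of 100 splits of the libraries passed as many lists, up to 17.

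Splits of the same libraries into groups of the same sizes were drawn 100 times per comparison, the real split included. For counts of genes chance is argued against in the pairwise comparisons and both averages, as in each 1 of 100 splits, the real one, reached the real value. The real count was 196 and the highest other 5 for novelty in controls, 393 and 34 for novelty in cKO mice, 131 and 86 for genotype in naive mice, 733 and 458 for genotype after novelty, 2017 and 1 for the genotype average and 1097 and 190 for the novelty average. With 1 library left out the real count fell to as low as 40 for genotype in naive mice and 324 for genotype after novelty. Both lie below the highest other split, so the margin there is narrow. For the other comparisons it stayed above. The splits were not refitted with a library left out. For the correlation of fold changes the real value was 0.439 and the highest other 0.419 for genotype, and 0.371 and 0.343 for novelty. In both, 1 of 100 pairs of splits, the real one, reached the real value, which argues against chance by a narrow margin. With 1 library left out the real values fell to as low as 0.361 and 0.318. For the interaction the real count was 0 edgeR calls, which every split reaches, so the count of genes tests nothing there. Of its 100 splits 1 called 109 genes, which may point to a structure of the samples that the 4 groups do not describe, though no test was made of this. For numbers of lists passing, few splits reached the real value for genotype after novelty (real 14, highest other 16, 2 of 100 splits) and the genotype average (18 and 17, 1 of 100 splits). This argues against chance in these 2, by a narrow margin and without adjustment over the comparisons. With an estimated correlation no list passed for genotype after novelty, and only glutamate receptors did in the genotype average. Chance cannot be excluded for genotype in naive mice (15 and 16, 5 of 100 splits), novelty in controls (6 and 16, 53 of 100), novelty in cKO mice (10 and 15, 20 of 100) and the novelty average (7 and 19, 53 of 100). The number of lists says little there, whatever the p of a single list.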

How the results depend on the processing

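The removal of the GC trend, the dentate marker covariate, the term for library numbers and the fits without control naive libraries 2 and 4 were chosen only after the data had been seen. No named gene that passed changed its direction under any setting. The balance of higher and lower calls turned in the genotype comparisons. Higher calls outnumbered lower ones after novelty with upper-quartile scaling (388 and 322), at an adjusted p below 0.1 (686 and 662) and without control novelty library 4 (537 and 408). In the genotype average they did so with upper-quartile scaling (1190 and 843), a mean of at least 10 reads (1014 and 1005) and without cKO novelty library 3 (1144 and 1066). Kat2a kept its direction and its side of the threshold under every setting, at -0.836 to -0.782 in naive mice and -0.797 to -0.746 after novelty when 1 library was left out. Of the comparisons of single named genes with their value under an alternative, 4834 stayed on the same side of the threshold, 529 no longer passed and 9 newly passed. Small changes can be missed with this number of libraries, since in simulated counts 29.9% (genotype after novelty) to 50.7% (novelty in cKO mice) of genes changed by the smallest simulated fold were recovered in the pairwise comparisons.

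Counts of genes in the pairwise comparisons moved with the setting, and the cause was not tested unless the setting itself shows it. DESeq2 called 373 genes against 196 for novelty in controls, 639 against 393 for novelty in cKO mice, 457 against 131 for genotype in naive mice and 1155 against 733 for genotype after novelty. With 1 surrogate variable the counts were 363 for novelty in controls, 599 for novelty in cKO mice and 293 for genotype in naive mice. A single fit of all groups, which shares the spread of 24 libraries, called 305 for novelty in controls and 322 for genotype in naive mice. Removing the GC trend gave 343 for novelty in controls and 256 for genotype in naive mice, and the dentate covariate gave 339 for genotype in naive mice. Without control naive libraries 2 and 4, which leaves fewer samples, 33 genes passed for genotype in naive mice. An adjusted p below 0.1, by its construction, gave 687 for novelty in cKO mice, 343 for genotype in naive mice, 1348 for genotype after novelty and 3031 for the genotype average. All other counts under settings that keep every library, apart from the block, stayed within 1.5 times their value.

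Leaving out 1 library gave 113 (without control novelty 2) to 255 genes for novelty in controls, 238 (without cKO naive 2) to 452 for novelty in cKO mice, 40 (without control naive 6) to 166 for genotype in naive mice and 324 (without control novelty 2) to 1025 for genotype after novelty. The averages over all 24 libraries ranged from 1480 to 2210 for genotype and from 850 to 1262 for novelty.

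The replicate block used the numbers in the titles as a factor. It called 97 genes for novelty in controls, 207 for novelty in cKO mice, 70 for genotype in naive mice and 398 for genotype after novelty. Pair by pair, libraries of the same number did not deviate together throughout. Correlations of deviations between libraries of the same number ran from -0.14 to 0.12 for novelty in controls, -0.2 to 0.3 for novelty in cKO mice, -0.21 to 0.43 for genotype in naive mice and -0.13 to 0.37 for genotype after novelty, and 1 library per comparison correlated best with its own number. The GC slope of the libraries did follow the numbers, with 1 to 3 against 4 and above (permutation p = 1e-05), so a processing step shared by number is not excluded, and it was not tested what the losses under the block come from. A term for numbers 4 and above gave 233 genes for novelty in controls, 395 for novelty in cKO mice, 171 for genotype in naive mice, 669 for genotype after novelty, 2147 for the genotype average, 1199 for the novelty average and 0 for the interaction. Of the main calls it kept 82.9% (genotype after novelty) to 99.8% (novelty average). List calls were lost as well. Under the block camera no longer passed NF-kappa-B genes (adjusted p = 0.101), endothelium (0.113) and neocortex markers (0.0796) for genotype after novelty. It also lost the p53 list in cKO mice (0.0845) and MHC genes in the novelty average (0.0564), among others. Under the term for numbers, camera lost NF-kappa-B genes for genotype after novelty (adjusted p = 0.0686), among others.

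The correlation of fold changes rose to 0.562 for genotype and 0.539 for novelty in genes with a mean count of at least 50, which leaves out genes with more counting noise. With an estimated correlation, 2 of 10 lists passed for novelty in cKO mice, 0 of 15 for genotype in naive mice, 0 of 14 for genotype after novelty, 0 of 6 for the interaction, 1 of 18 for the genotype average and 4 of 7 for the novelty average. The fry test passed 6 lists for novelty in cKO mice, 8 for genotype in naive mice, 7 for genotype after novelty and 0 for the interaction. In the genotype average fry passed the lists that camera passed, except MHC genes (fry adjusted p = 0.0641), the respiratory chain (0.266) and dentate markers (0.303). Its adjusted p was 5.29e-06 for glutamate receptors, 8.15e-05 for CA1 markers and 0.00255 for oligodendrocyte markers. Of the lists that passed camera in the novelty average, only MHC genes did not pass fry (adjusted p = 0.0752). Fry does not set a list against other genes, so it answers another question than camera. With 1 library left out, 6 to 10 lists passed for novelty in controls (10 without control naive 1), 9 to 15 for genotype after novelty (9 without cKO novelty 2) and 0 to 8 for the interaction (0 without cKO novelty 1). The cause of these differences was not tested.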

Other observations

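The exact permutation tests of list levels given here were chosen only after the data had been seen.

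In cKO mice the mean level of the 27 SAGA and ATAC subunits was 0.05 log2 CPM higher after novelty than in naive mice (exact two-sided permutation p = 0.000583, 0.0105 adjusted over the lists), with Atxn7 (0.39, SE 0.05) as the subunit that passed in edgeR. In controls the same difference was 0.02 (exact p = 0.214, adjusted 0.593). In cKO mice camera did not call this list (adjusted p = 0.0603). By the same exact test, immediate early genes were 0.94 (exact p = 0.000583), glucocorticoid-responsive genes 0.49 (exact p = 0.00117), heat shock and unfolded protein response genes 0.18 (exact p = 0.00117), sex-linked transcripts 0.15 (exact p = 0.00291) and p53 response genes 0.12 (exact p = 0.00583) higher in cKO mice after novelty. In controls the immediate early genes were 0.86, the glucocorticoid-responsive genes 0.54, the circadian clock genes 0.20 and the p53 response genes 0.17 higher, each at exact p = 0.00216. Heat shock genes were 0.14 higher in controls (exact p = 0.013, adjusted 0.0936) and clock genes 0.17 higher in cKO mice (exact p = 0.0146, adjusted 0.0751). Passing in 1 genotype alone thus does not show a response particular to it. Sex-linked transcripts differed by -0.03 in controls (exact p = 0.721). Whether the subunits differ in response between genotypes was tested by the interaction, in which the list did not pass (median difference 0.03, camera adjusted p = 0.333).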
